A study of Rattus norvegicus with 28 samples.

How the data were processed

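The data are gene expression profiles of left ventricle biopsies from 28 male rats, 1 array per sample as the labels give them. Sprague Dawley (SD) control rats gave 8 arrays. Double transgenic rats (dTGR), known as a model of angiotensin-dependent hypertension that carries human transgenes, gave 8 arrays after vehicle and 12 arrays after the stimulator of soluble guanylate cyclase named in the study title, at 3 mg/kg/day (treated dTGR). Per the labels, rats were assigned at 3.5 weeks of age, gavage ran once daily from 4 weeks of age, and hearts were taken at 7 weeks. The study design text gives 4 weeks of treatment, which does not match those ages, and no difference reported here uses the duration. Per the labels, 250 ng of total RNA of each sample was amplified and labelled with biotin by whole transcript kits for 1-colour arrays.

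The authors deposited 1 normalized intensity per probe and array, and RMA is named per the submitters' processing notes, with its version not given in the sources used here. The deposited intensity values are on a linear scale, from 1.90 to 162208, where RMA usually gives log2 values, and the scaling factor is not given in the sources used here. Log2 was taken before every test. The arrays had nearly equal distributions, with medians of intensity from 99.5 to 107, lower quartiles from 45.1 to 46.3 and upper quartiles from 651 to 670. No 2 arrays were identical. The number of arrays limits the precision of every value.

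Of the 36685 probes, 14824 carry 1 gene symbol in the annotation, 829 carry several and 21032 carry none. Probes with a mean log2 intensity above the 30th percentile of all probes (5.65, an intensity of 50.2) were kept, which left 25679 probes, 11691 of them with 1 symbol. The brightest probe stood for each gene, which gave 11493 genes. Spp1 and Prkg1 have no probe with that symbol alone and were not analysed here. The rat probes do not measure the human transgenes. Probes of gene families with close members (haemoglobins, the RT1 genes, metallothioneins, Reg3, Gbp and Oas genes, Klk10 and Sult1a1) were not checked for cross-hybridization.

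Differences were tested in R 4.3.3 with limma 3.58.1. All 28 arrays entered 1 linear model with a mean per group, moderated with an intensity trend, and each comparison was tested on both sides. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 11493 genes. Differences are on the log2 scale and stand with their standard error (SE), and levels stand with their standard deviation, which is written out, since SD stands for the control rats. The arrays carry no measure of background, so where a group mean lay under the filter level of 5.65, arrays of that group were raised to this level and the fold is given as at least that value. A count of arrays after a difference gives the arrays of the group named first that lay on that side of the mean of the other group. The p-values measure the spread between samples as the labels give them. No batch is given in the labels, and animal numbers differ between groups, so nothing was paired or blocked. Genotype cannot be separated from cohort or from gavage, since the SD controls were untreated per the labels. The animal numbers of vehicle and treated dTGR also form separate blocks, so treatment cannot be separated from any difference between those blocks.

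The comparisons, the tests, 30 gene lists (pathways of the pressure-loaded heart and of nitric oxide signalling, and markers of cell types the biopsy could hold) and the rule for named genes were chosen before the data were examined. For 29 lists, 16 of pathways and 13 of cell types, at least 5 genes were measured. The skeletal muscle list, with 3 of its 12 genes measured, was not tested. Among all lists, 5 genes belong to more than 1. Each list was tested against the other genes with camera in limma at a preset correlation of 0.01, adjusted over the 29 lists of a comparison, then again with an estimated correlation, and with fry, which tests whether a list's genes move on balance in one direction without comparing them with other genes. Counts of list genes adjusted over the list alone correct only over the genes of that list, and no list test uses them. The named genes are the 8 highest and 8 lowest called genes of the vehicle and treatment comparisons and the 6 highest and 6 lowest of treated dTGR against SD. They also include up to 3 called members of each list with the largest differences, the 8 strongest opposite calls, the 6 strongest genes of each other class of calls, and a fixed set that was reported called or not. Examples in the text were taken from these genes, and any other gene is named as such.

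The vehicle arrays serve in 2 of the comparisons and the SD arrays likewise, which creates overlap by itself. Overlaps were therefore set against the number from independent lists, 100 permutations of the residuals across arrays, and all 70 splits of the shared arrays into groups of equal size. A slope of treatment on disease differences was computed across genes with different vehicle arrays on each side, over 70 splits. Chance was tested with 100 seeded splits of the arrays of each comparison.

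The model was tested on simulated data with 200 genes changed, drawn at each gene's mean and residual spread. The simulated noise was independent between genes and had the same spread in all groups. The rates below therefore leave out correlation between genes and the wider spread of the vehicle arrays. A simulated log2 difference of 0.25 was called for 14.9% of the genes between treated and vehicle and 23.9% between treated and SD. This size was not simulated between vehicle and SD. A difference of 0.5 was called for 61.2% of the genes between vehicle and SD, 59.7% between treated and vehicle and 55.2% between treated and SD. A difference of 1 was called for 88.1%, 86.4% and 86.4%, and of the calls 3.49%, 5.31% and 6.78% were false. In a separate simulation of this kind with more genes changed, a slope of -0.5 was recovered as -0.47, and a slope of 0 as 0.00111.

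The alternatives tried were no filter and a filter at the median level, the mean of a gene's probes, every probe on its own, and quantile normalization applied again. Others were centring each array on its median, a robust prior, a prior without the intensity trend, array weights, a fit of only the 2 groups compared, a 1.5-fold minimum and an adjusted p under 0.01. Each array was also left out in turn. Leaving out vehicle replicates 6 and 7 together was added after their values were seen. Gene positions used for neighbour counts are those of the rat assembly GRCr8. Single arrays were tested as far from their group with Dixon's test in groups of 8, and the group of 12 was not tested this way.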

Results

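Left ventricles of 28 male rats were profiled on whole transcript arrays. The 3 groups were SD controls (8 arrays), dTGR given vehicle (8 arrays) and dTGR given the soluble guanylate cyclase stimulator of the study title (12 arrays). The first principal component held 19.0% of the variance and the next held 11.4%. SD arrays lay between -22.9 and -17.1 on the first component, treated dTGR between -7.94 and 4.72, and vehicle dTGR between -2.92 and 41.3. Vehicle replicates 6 (-0.84) and 7 (-2.92) lay among the treated arrays, replicate 3 lay at 10.2, and the other 5 lay between 28.2 and 41.3.

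**Figure D1:**
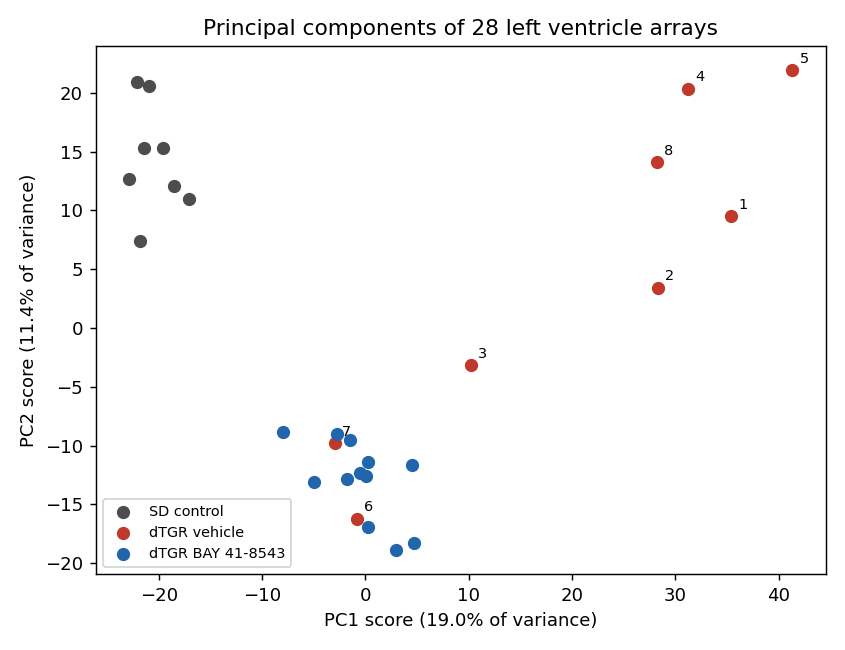
Scores of the 28 arrays on the first component (19.0% of the variance, horizontal) and the next (11.4%, vertical), from log2 intensities of 11493 genes, with a point per array coloured by group. SD arrays lie between -22.9 and -17.1 on the horizontal axis, treated dTGR between -7.94 and 4.72, and vehicle dTGR between -2.92 and 41.3, with vehicle replicates 6 and 7 among the treated arrays.

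The comparison of vehicle-treated dTGR with SD controls asks how gene expression differs in the transgenic heart. Nppa, which encodes atrial natriuretic peptide, was 13.9-fold higher in the dTGR ventricle (log2 3.80 ± 0.47, adjusted p = 4.21e-07, 8 of 8 arrays), and Nppb, which encodes B-type natriuretic peptide, was 3.05-fold higher (log2 1.61 ± 0.23, adjusted p = 3.39e-06, 8 of 8 arrays). The stress-induced metallothionein gene Mt2A was 14.8-fold higher (log2 3.88 ± 0.60, adjusted p = 1.16e-05, 7 of 8 arrays), and the matrix-associated growth factor gene Ccn2 was 4.83-fold higher (log2 2.27 ± 0.30, adjusted p = 1.23e-06, 8 of 8 arrays). Kcnd2, a subunit of the transient outward potassium channel, was 3.45-fold lower (log2 -1.78 ± 0.23, adjusted p = 5.45e-07, 8 of 8 arrays). Of list members measured, 22 of 33 genes of fatty acid uptake and oxidation were lower, and 10 of 20 macrophage markers and 10 of 22 cell cycle genes were higher. Of 11493 genes, 2731 were called, 1385 higher and 1346 lower, and 574 and 452 of these differed by at least 1.5-fold.

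Among the largest differences, Reg3b, a secreted lectin of the regenerating islet family, had a log2 difference of 6.12 ± 0.56 and its relative Reg3g one of 3.42 ± 0.66. The cardiac ankyrin repeat genes Ankrd23 (3.46 ± 0.16) and Ankrd2 (3.39 ± 0.53), the sodium channel subunit Scn3b (3.25 ± 0.26) and the phosphatase gene Dusp15 (3.23 ± 0.32) followed. Among the lowest were the glucagon receptor gene Gcgr (-3.19 ± 0.22), Art1 (-2.46 ± 0.40), the potassium channel gene Kcna2 (-2.37 ± 0.21), Ddit4l (-2.18 ± 0.29), the haemoglobin gene Hba-a3 (-2.19 ± 0.29) and the mesothelial genes Msln and Upk3b. Each of these 7 genes was below the SD mean in all 8 vehicle arrays.

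The hypertrophy and fetal gene program had 6 of 7 measured genes higher, 1 lower and 0 not called. With 6 higher and 1 lower adjusted over the list alone, camera gave adjusted p = 3.9e-06, and adjusted p = 0.13 with an estimated correlation. Besides Nppa and Nppb, the higher genes included skeletal alpha-actin Acta1 (1.29 ± 0.12), beta-myosin heavy chain Myh7 (1.00 ± 0.24) and Ankrd1 (0.41 ± 0.05), and the lower one was the creatine kinase gene Ckb, which was named after its value was seen. Nppa varied widely among the SD arrays (11.96 ± 1.90, standard deviation, n = 8), which ranged from 9.92 to 14.9. Extracellular matrix and fibrosis had 13 of 28 measured genes higher, 2 lower and 13 not called. With 13 higher and 3 lower adjusted over the list alone, camera gave adjusted p = 0.000641, and adjusted p = 0.322 with an estimated correlation. Thbs4 (2.55 ± 0.55), Ccn2 and the protease inhibitor gene Timp1 (1.78 ± 0.31) were higher, while the fibrillar collagen genes Col1a1 (-0.19 ± 0.23) and Col3a1 (-0.30 ± 0.20) were not called. Postn (1.28 ± 0.44) was called, but it lost its call without SD replicates 1, 3, 7 or 8 or vehicle replicates 1 or 2, or with array weights, a robust prior, a prior without the trend or every probe on its own, at adjusted p from 0.05 to 0.0864. Tgfb1 (0.35 ± 0.11) was called, but it lost its call without SD replicate 8, at an adjusted p of 0.0528. Cell cycle had 10 of 22 measured genes higher, 0 lower and 12 not called. With 11 higher and 0 lower adjusted over the list alone, camera gave adjusted p = 0.000641, and adjusted p = 0.267 with an estimated correlation. Rrm2 (1.06 ± 0.26), Prc1 (0.96 ± 0.21) and Kif20a (0.83 ± 0.21) were among the higher genes.

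Inflammatory cytokines and adhesion had 13 of 27 measured genes higher, 3 lower and 11 not called. With 14 higher and 3 lower adjusted over the list alone, camera gave adjusted p = 0.00562, and adjusted p = 0.267 with an estimated correlation. With the filter at the median, the inflammatory list lost its call, at an adjusted p of 0.0589. The prostaglandin synthase gene Ptgs2 (1.90 ± 0.37), the neutrophil chemokine gene Cxcl2 (at least 2.03-fold), the oncostatin M receptor gene Osmr (1.47 ± 0.19) and the monocyte chemokine gene Ccl2 (0.85 ± 0.26) were higher. Ccl2 lost its call with only the 2 groups, at an adjusted p of 0.0508. The interferon response had 0 of 15 measured genes higher, 8 lower and 7 not called. With 8 lower and 1 higher adjusted over the list alone, camera gave adjusted p = 0.000294, and adjusted p = 0.267 with an estimated correlation. Psmb9 (-1.24 ± 0.14), Oasl (-1.16 ± 0.31) and Irf7 (-1.14 ± 0.23) were among the lower genes. Complement and coagulation had 4 of 10 measured genes higher, 0 lower and 6 not called. With 5 higher and 0 lower adjusted over the list alone, camera gave adjusted p = 0.0265, and adjusted p = 0.267 with an estimated correlation. The plasminogen activator genes Plat (0.86 ± 0.10) and Plau (0.71 ± 0.21) were higher. Without vehicle replicate 5, the complement list lost its call, at an adjusted p of 0.0526. Antigen presentation by MHC class II had 2 of 9 measured genes higher, 4 lower and 3 not called. With 5 lower and 2 higher adjusted over the list alone, camera gave adjusted p = 0.0359, and adjusted p = 0.322 with an estimated correlation. RT1-Db1 (3.23 ± 0.39) was higher while RT1-Bb (-1.71 ± 0.22) and RT1-DMb (-0.96 ± 0.12) were lower. Without SD replicates 1 or 4 or vehicle replicate 4, or with the filter at the median, the MHC class II list lost its call, at adjusted p from 0.0517 to 0.0599.

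Fatty acid uptake and oxidation had 1 of 33 measured genes higher, 22 lower and 10 not called. With 23 lower and 2 higher adjusted over the list alone, camera gave adjusted p = 2.06e-10, and adjusted p = 0.149 with an estimated correlation. Ech1 (-0.70 ± 0.10) and the uncoupling protein gene Ucp3 (-1.03 ± 0.23) were lower, and the higher gene was Pdk4 (1.09 ± 0.28), a kinase that inhibits pyruvate dehydrogenase. Oxidative phosphorylation had 0 of 43 measured genes higher, 8 lower and 35 not called. With 0 higher and 4 lower adjusted over the list alone, camera gave adjusted p = 0.000294, and adjusted p = 0.267 with an estimated correlation. Ndufa5 (-0.30 ± 0.07) and Uqcrq (-0.24 ± 0.07) were lower, and the list median was -0.10. The tricarboxylic acid cycle had 0 of 15 measured genes higher, 3 lower and 12 not called. With 3 lower and 0 higher adjusted over the list alone, camera gave adjusted p = 0.0214, and adjusted p = 0.31 with an estimated correlation. Pyruvate carboxylase Pc (-0.64 ± 0.07) was among the lower genes. Calcium handling and ion channels had 0 of 20 measured genes higher, 11 lower and 9 not called, and this was the only list of the comparison called with either correlation. With 12 lower and 0 higher adjusted over the list alone, camera gave adjusted p = 1.53e-06, and adjusted p = 0.00786 with an estimated correlation. Kcnd2, the sodium channel subunit Scn4b (-1.70 ± 0.27), the T-type calcium channel gene Cacna1h (-1.32 ± 0.17) and the sarcoplasmic calcium pump Atp2a2 (-0.18 ± 0.05) were lower, and Pln (-0.04 ± 0.04) was not called.

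Oxidative stress and redox had 7 of 17 measured genes higher, 2 lower and 8 not called. With 7 higher and 2 lower adjusted over the list alone, the list was not called (adjusted p = 0.0694). The haem oxygenase gene Hmox1 (1.63 ± 0.33) was higher, and Ncf1 (-1.31 ± 0.11), a subunit of the phagocyte oxidase, was lower. Without vehicle replicates 6 or 7, without vehicle replicates 6 and 7 together, or with fry, the redox list was called, at adjusted p from 0.00734 to 0.0395. Nitric oxide and cyclic GMP signalling had 2 of 20 measured genes higher, 3 lower and 15 not called. With 3 lower and 2 higher adjusted over the list alone, the list was not called (adjusted p = 0.684). Its median of 0.01 and its mean of -0.03 differed in sign. The endothelial synthase gene Nos3 (0.41 ± 0.08) and the guanylate cyclase subunit Gucy1b1 (0.32 ± 0.10) were higher and Nos2 (-0.71 ± 0.21) was lower, while Gucy1a1 (-0.02 ± 0.11), Pde5a (0.18 ± 0.10) and Npr3 (0.32 ± 0.27) were not called. Gucy1b1 lost its call with only the 2 groups, at an adjusted p of 0.0623. The renin-angiotensin-aldosterone system had 2 of 10 measured genes higher, 2 lower and 6 not called. With 2 higher and 2 lower adjusted over the list alone, the list was not called (adjusted p = 0.99). Ace, the gene of angiotensin-converting enzyme, was higher (1.30 ± 0.21), and the rat genes Agt (0.39 ± 0.21) and Agtr1a (0.0039 ± 0.21) were not called. Glucose uptake and glycolysis had 3 of 13 measured genes higher, 5 lower and 5 not called. With 5 lower and 3 higher adjusted over the list alone, the list was not called (adjusted p = 0.0861). With fry or no filter, the glucose uptake and glycolysis list was called, at adjusted p from 0.000749 to 0.046. The glucose transporter gene Slc2a1 (0.89 ± 0.14) was higher and the muscle enolase Eno3 (-1.11 ± 0.15) was lower.

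Monocyte and macrophage markers had 10 of 20 measured genes higher, 2 lower and 8 not called. With 10 higher and 2 lower adjusted over the list alone, camera gave adjusted p = 0.000294, and adjusted p = 0.273 with an estimated correlation. Gpnmb (1.70 ± 0.26), Lgals3 (1.38 ± 0.18) and C1qb (1.24 ± 0.17) were higher. Markers of T, B and natural killer lymphocytes had 0 of 17 measured genes higher, 6 lower and 11 not called. With 6 lower and 0 higher adjusted over the list alone, camera gave adjusted p = 0.0162, and adjusted p = 0.194 with an estimated correlation. Klrd1 (-1.01 ± 0.22), Klrb1a (-0.90 ± 0.20) and Cd3g (-0.78 ± 0.19) were lower. Endothelial cell markers had 4 of 13 measured genes higher, 0 lower and 9 not called. With 4 higher and 0 lower adjusted over the list alone, camera gave adjusted p = 0.0297, and adjusted p = 0.194 with an estimated correlation. Smooth muscle and pericyte markers had 4 of 8 measured genes higher, 0 lower and 4 not called. With 4 higher and 0 lower adjusted over the list alone, camera gave adjusted p = 0.00794, and adjusted p = 0.267 with an estimated correlation. Ecscr (0.71 ± 0.11), Esam (0.67 ± 0.10), Cspg4 (0.97 ± 0.09) and Mcam (0.58 ± 0.08) were among the higher genes. Mesothelial and epicardial markers had 0 of 6 measured genes higher, 4 lower and 2 not called. With 0 higher and 4 lower adjusted over the list alone, camera gave adjusted p = 0.00115, and adjusted p = 0.149 with an estimated correlation. Lrrn4 (at least 3.76-fold), Msln (-2.34 ± 0.37) and Upk3b (-2.20 ± 0.34) were lower. Cardiomyocyte markers had 1 of 11 measured genes higher, 4 lower and 6 not called. With 4 lower and 1 higher adjusted over the list alone, the list was not called (adjusted p = 0.131). With fry, the cardiomyocyte list was called, at an adjusted p of 0.000901. Myh6 (-0.31 ± 0.08) was lower. Fibroblast markers had 4 of 13 measured genes higher, 2 lower and 7 not called. With 5 higher and 2 lower adjusted over the list alone, the list was not called (adjusted p = 0.513).

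Neutrophil markers had 2 of 6 measured genes higher, 0 lower and 4 not called. With 3 higher and 0 lower adjusted over the list alone, the list was not called (adjusted p = 0.0523). Lcn2 (2.58 ± 0.37) was higher. Without SD replicates 1, 3, 5 or 6 or vehicle replicates 2, 3, 6 or 7, without vehicle replicates 6 and 7 together, or with fry or quantile normalization again, the neutrophil list was called, at adjusted p from 0.00282 to 0.0488. Erythroid and blood markers had 0 of 7 measured genes higher, 2 lower and 5 not called. With 0 higher and 4 lower adjusted over the list alone, the list was not called (adjusted p = 0.0533). Hba-a1 (-1.04 ± 0.26) and Hbb-b1 (-1.22 ± 0.29) were lower. Without SD replicates 1, 2 or 3, vehicle replicates 2, 5 or 8 or treated replicates 4 or 5, or with arrays centred on their medians, fry, no filter or only the 2 groups, the erythroid list was called, at adjusted p from 0.0172 to 0.0491. Atrial myocyte markers had 2 of 7 measured genes higher, 3 lower and 2 not called. With 3 lower and 2 higher adjusted over the list alone, the list was not called (adjusted p = 0.719). Their mean of 0.15 had the opposite sign to their median of -0.10 and their test. Of these, Myl7, the atrial light chain, was lower (-1.77 ± 0.36) where Nppa was higher. Camera called 16 lists, 8 higher and 8 lower, fry called 21, and 1 held with an estimated correlation.

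The comparison of treated with vehicle dTGR asks how gene expression differs under the guanylate cyclase stimulator in the transgenic heart. Hmox1 was 3.65-fold lower in treated hearts (log2 -1.87 ± 0.30, adjusted p = 0.000481, 12 of 12 arrays) and Mt2A was 8.48-fold lower (log2 -3.08 ± 0.55, adjusted p = 0.000743, 12 of 12 arrays). The neuropeptide gene Gal was at least 5.05-fold lower (adjusted p = 0.000659, 12 of 12 arrays) and Fos, an immediate early transcription factor, was 4.54-fold lower (log2 -2.18 ± 0.54, adjusted p = 0.00847, 12 of 12 arrays). Without vehicle replicate 1 the log2 difference of Fos was -1.51. The apelin receptor gene Aplnr was 3.38-fold higher (log2 1.76 ± 0.32, adjusted p = 0.000939, 12 of 12 arrays) and Kcnd2 was 2.02-fold higher (log2 1.01 ± 0.21, adjusted p = 0.00217, 12 of 12 arrays). The natriuretic peptide genes Nppa (-0.06 ± 0.43) and Nppb (0.23 ± 0.21) were not called. Of 11493 genes, 1125 were called, 617 higher and 508 lower, and 196 and 218 of these differed by at least 1.5-fold.

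Among the lowest genes were also Angptl4 (-2.60 ± 0.47), an inhibitor of lipoprotein lipase, Ankrd2 (-2.24 ± 0.49), Mt1f (-2.20 ± 0.36), Sult1a1 (-2.13 ± 0.38) and Tgm1 (-2.08 ± 0.39). Each was below the vehicle mean in all 12 treated arrays. Among the highest were Klk10 (1.57 ± 0.39), Ddit4l (1.43 ± 0.26), Lrrc3b (1.42 ± 0.28), Cited4 (1.23 ± 0.30), the relaxin receptor gene Rxfp1 (1.23 ± 0.21) and Smim5 (1.22 ± 0.26). Each was above the vehicle mean in all 12 treated arrays. In the vehicle group the level of Hmox1 was widely spread (10.92 ± 1.34, standard deviation, n = 8), against 9.05 ± 0.24 (n = 12) in treated dTGR and 9.29 ± 0.18 (n = 8) in SD. Hmox1 was 8.93 in vehicle replicate 6 and 8.78 in replicate 7, and between 10.8 and 12.1 in the other 6. The vehicle levels of Fos (9.44 ± 2.35, standard deviation), Gal (8.01 ± 2.19) and Ankrd2 (10.35 ± 2.02) were also widely spread. Their lowest vehicle arrays stood at 7.07, 5.05 and 7.25. For such genes the SE, pooled over all 3 groups, is smaller than the vehicle arrays alone would give, and counts of arrays refer only to the vehicle mean.

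**Figure D2:**
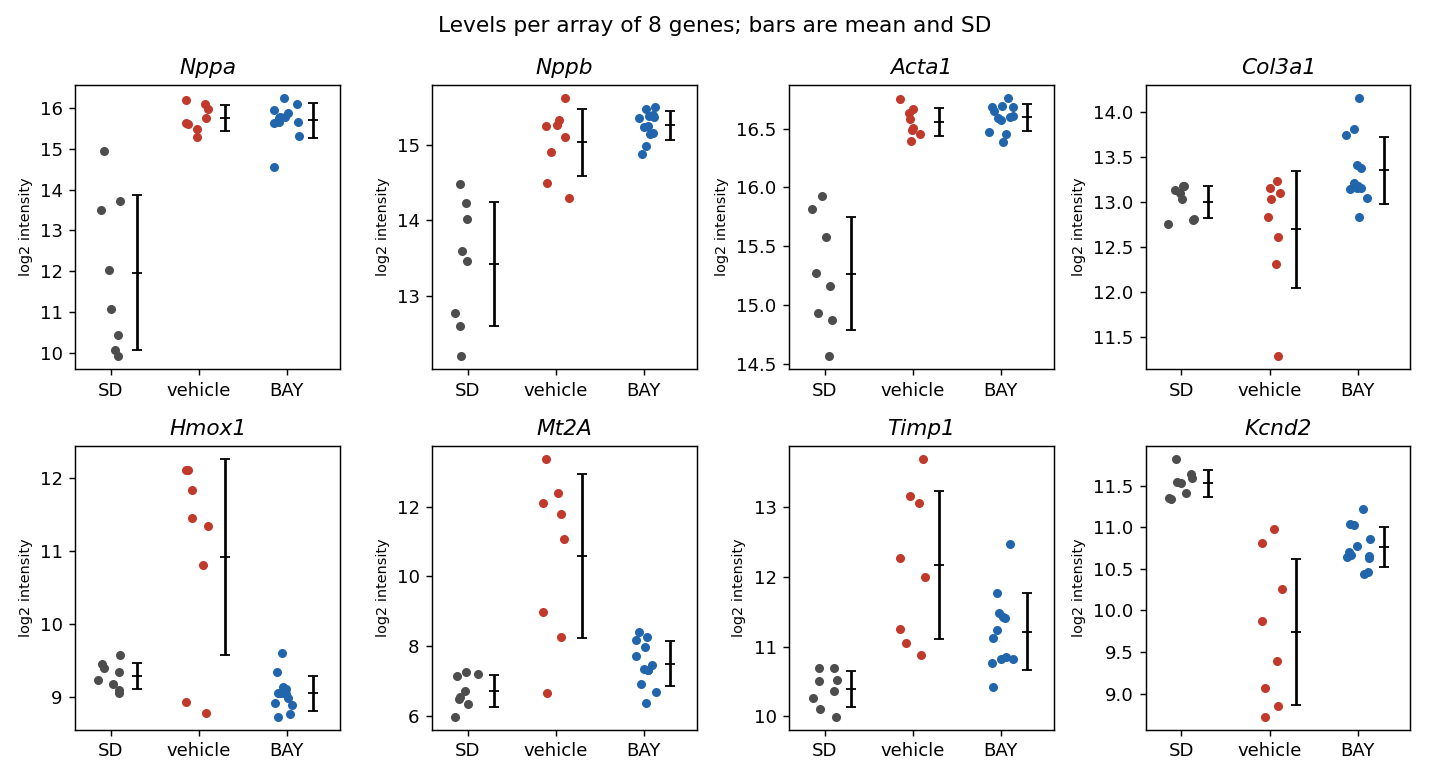
Log2 intensity (vertical) of Nppa, Nppb, Acta1, Col3a1, Hmox1, Mt2A, Timp1 and Kcnd2 in SD (8 arrays), vehicle dTGR (8) and treated dTGR (12), with a point per array, the group mean as a line and the standard deviation as a bar. Nppa stands at 15.76 in vehicle and 15.70 in treated dTGR against 11.96 in SD, while Hmox1 stands at 10.92, 9.05 and 9.29.

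Oxidative stress and redox had 1 of 17 measured genes higher, 8 lower and 8 not called, and this was the only list of the comparison called with either correlation. With 9 lower and 1 higher adjusted over the list alone, camera gave adjusted p = 1.58e-05, and adjusted p = 0.0416 with an estimated correlation. Besides Hmox1 and Mt2A, Txnip (-0.51 ± 0.11), which binds thioredoxin, was lower. Inflammatory cytokines and adhesion had 1 of 27 measured genes higher, 9 lower and 17 not called. With 11 lower and 4 higher adjusted over the list alone, camera gave adjusted p = 0.0272, and adjusted p = 0.524 with an estimated correlation. Cxcl2 (at least 2.06-fold), Il6 (-1.32 ± 0.30) and Osmr (-1.02 ± 0.17) were lower and Ccl2 (-0.01 ± 0.24) was not called. Without vehicle replicates 1 or 5 or treated replicate 5, or with the filter at the median or fry, the inflammatory list lost its call, at adjusted p from 0.0523 to 0.239. Complement and coagulation had 0 of 10 measured genes higher, 2 lower and 8 not called. With 4 lower and 1 higher adjusted over the list alone, camera gave adjusted p = 0.0463, and adjusted p = 0.524 with an estimated correlation. Without SD replicate 1, vehicle replicates 1, 2 or 5 or treated replicates 2, 4, 5, 6, 9 or 12, or with array weights, arrays centred on their medians, a robust prior, a prior without the trend, the filter at the median, fry or only the 2 groups, the complement list lost its call, at adjusted p from 0.0502 to 0.128. The interferon list had 2 of 15 measured genes higher, 1 lower and 12 not called. With 2 higher and 1 lower adjusted over the list alone, the list was not called (adjusted p = 0.142). Psmb9 (0.51 ± 0.13) was higher and Ifit3 (-0.56 ± 0.14) was lower. Without vehicle replicate 7, or without vehicle replicates 6 and 7 together, the interferon list was called, at adjusted p from 0.028 to 0.0444. The MHC class II list had 1 of 9 measured genes higher, 0 lower and 8 not called. With 3 higher and 1 lower adjusted over the list alone, the list was not called (adjusted p = 0.0609). The higher gene was Cd74 (0.26 ± 0.07). Without vehicle replicate 1 or treated replicates 2 or 6, or with no filter or only the 2 groups, the MHC class II list was called, at adjusted p from 0.0302 to 0.047.

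Extracellular matrix and fibrosis had 7 of 28 measured genes higher, 1 lower and 20 not called. With 10 higher and 2 lower adjusted over the list alone, camera gave adjusted p = 0.0148, and adjusted p = 0.594 with an estimated correlation. The lysyl oxidase gene Loxl1 (1.01 ± 0.26) and the collagen gene Col3a1 (0.66 ± 0.18) were higher in treated hearts, and Ccn2 (0.30 ± 0.28), Postn (0.30 ± 0.41) and Tgfb1 (0.05 ± 0.10) were not called. Without vehicle replicate 5 or treated replicate 3, or with fry, the matrix list lost its call, at adjusted p from 0.0523 to 0.165. The lower gene was Timp1 (-0.96 ± 0.28), and it lost its call without vehicle replicates 1, 2, 4 or 5, or with a robust prior, every probe on its own or only the 2 groups, at adjusted p from 0.0501 to 0.0869. Col1a1 (0.63 ± 0.21) was not called, and it was called without vehicle replicates 1, 3, 6 or 7, or with the filter at the median or quantile normalization again, at adjusted p from 0.0284 to 0.048. Fibroblast markers had 4 of 13 measured genes higher, 1 lower and 8 not called. With 6 higher and 2 lower adjusted over the list alone, camera gave adjusted p = 0.0272, and adjusted p = 0.524 with an estimated correlation. Fap (0.64 ± 0.15) and Lum (0.61 ± 0.15) were higher and Tcf21 (-0.69 ± 0.18) was lower. Without vehicle replicate 5 or treated replicate 3, or with the filter at the median or fry, the fibroblast list lost its call, at adjusted p from 0.0537 to 0.0629. Cell cycle had 1 of 22 measured genes higher, 0 lower and 21 not called. With 1 higher and 0 lower adjusted over the list alone, camera gave adjusted p = 0.0202, and adjusted p = 0.524 with an estimated correlation. Without vehicle replicate 5, or with the filter at the median or fry, the cell cycle list lost its call, at adjusted p from 0.0523 to 0.0629.

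Calcium handling and ion channels had 5 of 20 measured genes higher, 1 lower and 14 not called. With 8 higher and 1 lower adjusted over the list alone, camera gave adjusted p = 0.0391, and adjusted p = 0.386 with an estimated correlation. Scn4b (1.09 ± 0.25) was higher beside Kcnd2, and Atp2a2 (-0.04 ± 0.04) and Pln (-0.07 ± 0.04) were not called. Without vehicle replicates 1, 2 or 5 or treated replicates 4, 5 or 6, or with the filter at the median, the calcium and channel list lost its call, at adjusted p from 0.0522 to 0.0817. The hypertrophy list had 0 of 7 measured genes higher, 0 lower and 7 not called. With 0 higher and 0 lower adjusted over the list alone, the list was not called (adjusted p = 0.86). Its mean of -0.02 and its median of 0.04 differed in sign. Acta1 (0.04 ± 0.11), Ankrd1 (0.01 ± 0.04) and Myh7 (-0.57 ± 0.22) were not called. Myh7 was called without SD replicate 7, or with only the 2 groups, at adjusted p from 0.0287 to 0.0437. Fatty acid uptake and oxidation had 2 of 33 measured genes higher, 3 lower and 28 not called. With 3 higher and 3 lower adjusted over the list alone, the list was not called (adjusted p = 0.372). Pdk4 (-1.50 ± 0.26) and Cpt1a (-0.41 ± 0.09) were lower and the receptor gene Ppara (0.37 ± 0.07) was higher. Oxidative phosphorylation (adjusted p = 0.51, 0 of 43 genes called) and the tricarboxylic acid cycle (adjusted p = 0.951, 0 of 15 genes called) were not called, and 0 genes of either passed adjusted over the list alone. Glucose uptake and glycolysis had 4 of 13 measured genes higher, 1 lower and 8 not called. With 5 higher and 1 lower adjusted over the list alone, the list was not called (adjusted p = 0.214). Eno3 (0.73 ± 0.13) was higher.

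Nitric oxide and cyclic GMP signalling, the pathway of the drug's target, had 2 of 20 measured genes higher, 1 lower and 17 not called. With 4 higher and 1 lower adjusted over the list alone, the list was not called (adjusted p = 0.167). Nos2 (1.02 ± 0.19) and Ddah2 (0.43 ± 0.08) were higher, while Gucy1a1 (0.07 ± 0.10), Gucy1b1 (0.12 ± 0.09), Pde5a (0.17 ± 0.09) and Npr3 (0.53 ± 0.24) were not called. The renin-angiotensin-aldosterone system had 1 of 10 measured genes higher, 1 lower and 8 not called. With 2 lower and 1 higher adjusted over the list alone, the list was not called (adjusted p = 0.61). Ace (-1.02 ± 0.19) was lower, Nr3c1 (0.31 ± 0.07) was higher and Agt (-0.30 ± 0.19) and Agtr1a (-0.16 ± 0.19) were not called.

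Monocyte and macrophage markers had 1 of 20 measured genes higher, 4 lower and 15 not called. With 6 lower and 3 higher adjusted over the list alone, camera gave adjusted p = 0.0288, and adjusted p = 0.594 with an estimated correlation. C1qb (-0.76 ± 0.15), C1qc (-0.78 ± 0.17) and Lyve1 (-0.74 ± 0.13) were lower. Without vehicle replicates 1, 2 or 5 or treated replicates 5 or 9, or with the filter at the median or fry, the macrophage list lost its call, at adjusted p from 0.0507 to 0.268. Neutrophil markers had 0 of 6 measured genes higher, 2 lower and 4 not called. With 3 lower and 0 higher adjusted over the list alone, camera gave adjusted p = 0.00335, and adjusted p = 0.217 with an estimated correlation. Mmp8 (-1.18 ± 0.30) and S100a9 (-0.91 ± 0.23) were lower. Endothelial cell markers had 2 of 13 measured genes higher, 5 lower and 6 not called. With 6 lower and 2 higher adjusted over the list alone, camera gave adjusted p = 0.0463, and adjusted p = 0.386 with an estimated correlation. Sox17 (-0.63 ± 0.11) and Flt1 (-0.51 ± 0.10) were lower and Emcn (0.46 ± 0.12) was higher. Without SD replicate 1, vehicle replicates 1, 2, 3, 4, 5 or 8 or treated replicates 3, 5, 6, 9, 11 or 12, or with arrays centred on their medians, a prior without the trend or the filter at the median, the endothelial list lost its call, at adjusted p from 0.0502 to 0.0817. The lists of cardiomyocytes (adjusted p = 0.734), smooth muscle cells and pericytes (adjusted p = 0.204), lymphocytes (adjusted p = 0.265), erythroid cells (adjusted p = 0.265), atrial myocytes (adjusted p = 0.86) and mesothelial cells (adjusted p = 0.546) were not called. The cardiomyocyte list's mean of 0.00256 and its median of -0.01 differed in sign.

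Camera called 10 lists, 4 higher and 6 lower, fry called 4, and 1 held with an estimated correlation. The count of 1125 genes was 659 without vehicle replicate 4 and 733 without vehicle replicate 5, and the 10 lists were 6 without vehicle replicate 1 or 2, 2 without vehicle replicate 5 and 5 without treated replicate 5. Without vehicle replicates 6 and 7 together, a choice made after seeing the data, 2065 genes were called.

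**Figure D3:**
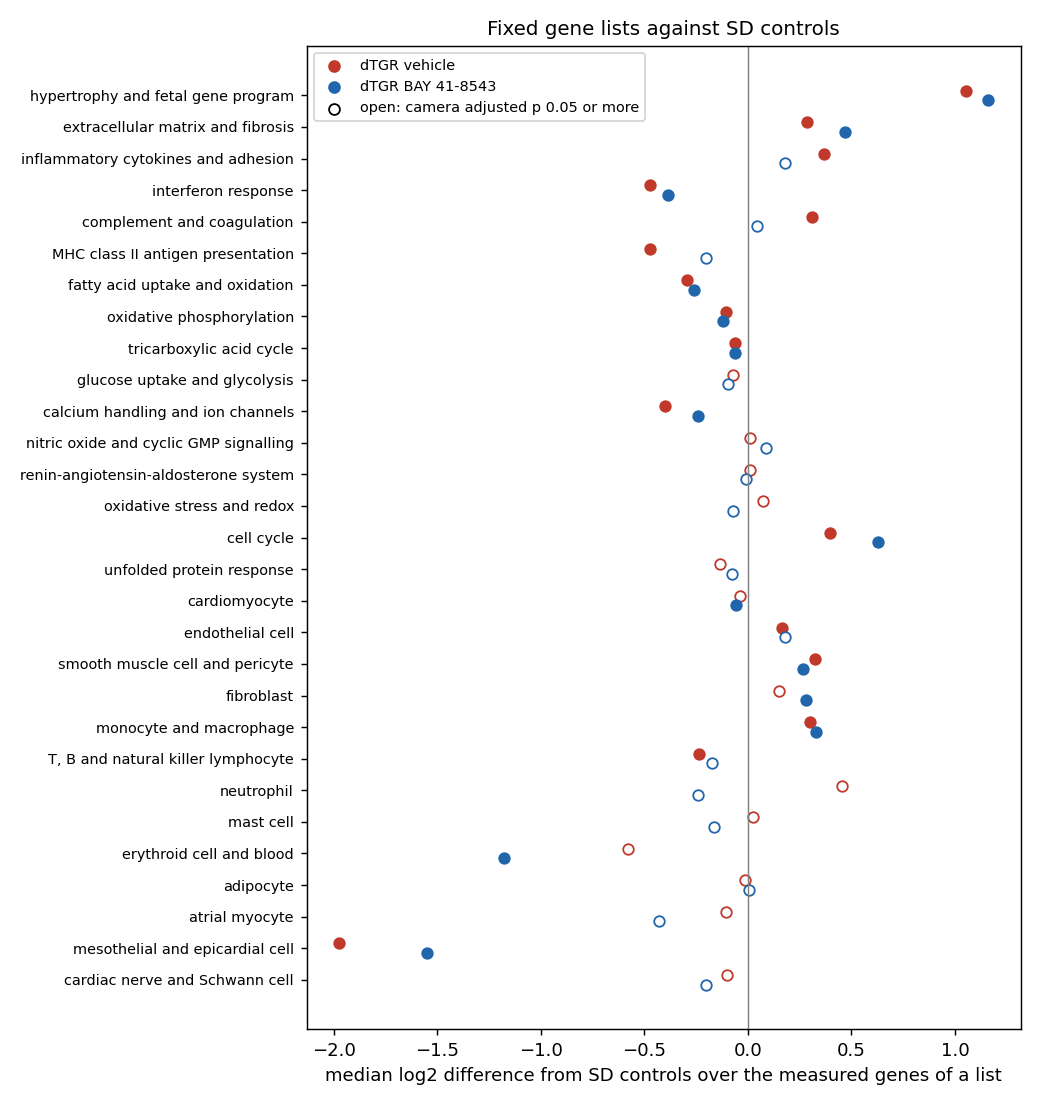
Median log2 difference of each of the 29 tested lists from SD (horizontal), for vehicle dTGR and treated dTGR, with a point per list and comparison and filled points where camera called the list. The hypertrophy list stands at 1.05 in vehicle and 1.16 in treated dTGR and the mesothelial list at -1.97 and -1.55.

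The comparison of treated dTGR with SD controls asks which differences from the control heart were present under treatment. Nppa was 13.4-fold higher in treated dTGR than in SD (log2 3.74 ± 0.43, adjusted p = 1.26e-07, 12 of 12 arrays), Nppb was 3.57-fold higher (log2 1.84 ± 0.21, adjusted p = 9.75e-08, 12 of 12 arrays) and Acta1 was 2.51-fold higher (log2 1.33 ± 0.11, adjusted p = 5.85e-10, 12 of 12 arrays). The matrix genes Thbs4, 10.2-fold higher (log2 3.35 ± 0.51, adjusted p = 1.09e-05, 12 of 12 arrays), and Ccn2, 5.96-fold higher (log2 2.57 ± 0.28, adjusted p = 3.63e-08, 12 of 12 arrays), also differed. Hmox1 (-0.23 ± 0.30) and Mt2A (0.80 ± 0.55) were not called. Mt2A was called with only the 2 groups, at an adjusted p of 0.0153. Of 11493 genes, 2001 were called, 1096 higher and 905 lower, and 386 and 216 of these differed by at least 1.5-fold.

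The highest genes also included Reg3b (4.23 ± 0.51), Reg3g (3.56 ± 0.60), RT1-Db1 (3.55 ± 0.35) and the guanylate-binding protein gene Gbp6 (at least 7.48-fold). The lowest were Hba-a3 (-2.45 ± 0.26), Gcgr (-2.17 ± 0.20), the alcohol dehydrogenase gene Adh1c (-2.10 ± 0.18), Kcna2 (-2.00 ± 0.19), Myl7 (-1.99 ± 0.33) and Upk3b (-1.89 ± 0.31), each below the SD mean in all 12 treated arrays.

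With either correlation, 5 lists were called. Hypertrophy had 5 of 7 measured genes higher, 0 lower and 2 not called. With 5 higher and 0 lower adjusted over the list alone, camera gave adjusted p = 2.74e-08, and adjusted p = 0.0284 with an estimated correlation. Cell cycle had 15 of 22 measured genes higher, 0 lower and 7 not called. With 17 higher and 0 lower adjusted over the list alone, camera gave adjusted p = 5.9e-10, and adjusted p = 0.0334 with an estimated correlation. Rrm2 (1.48 ± 0.23) and Kif20a (1.29 ± 0.19) were higher. Smooth muscle and pericyte markers had 4 of 8 measured genes higher, 0 lower and 4 not called. With 6 higher and 0 lower adjusted over the list alone, camera gave adjusted p = 7.05e-06, and adjusted p = 0.0334 with an estimated correlation. Cspg4 (0.80 ± 0.09) and Mcam (0.75 ± 0.07) were higher. Fatty acid uptake and oxidation had 0 of 33 measured genes higher, 24 lower and 9 not called. With 26 lower and 0 higher adjusted over the list alone, camera gave adjusted p = 8.34e-19, and adjusted p = 0.0284 with an estimated correlation. Ucp3 (-1.42 ± 0.21) and Ech1 (-0.68 ± 0.09) were lower. Calcium handling and ion channels had 0 of 20 measured genes higher, 10 lower and 10 not called. With 12 lower and 1 higher adjusted over the list alone, camera gave adjusted p = 8.4e-06, and adjusted p = 0.025 with an estimated correlation. Cacna1h (-1.49 ± 0.16), Kcnd2 (-0.77 ± 0.21) and Atp2a2 (-0.22 ± 0.04) were lower. Pln (-0.11 ± 0.04) was called, but it lost its call without SD replicates 3, 5, 6, 7 or 8 or treated replicates 1, 3, 5, 7, 9, 10 or 11, or with arrays centred on their medians, a prior without the trend or every probe on its own, at adjusted p from 0.0551 to 0.0963. Myh7 (0.43 ± 0.22) was not called. Myh6 (-0.15 ± 0.07) was not called, and it was called without treated replicate 9, at an adjusted p of 0.0131.

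Extracellular matrix and fibrosis had 17 of 28 measured genes higher, 1 lower and 10 not called. With 19 higher and 1 lower adjusted over the list alone, camera gave adjusted p = 4.48e-11, and adjusted p = 0.11 with an estimated correlation. Loxl1 (1.24 ± 0.26), Postn (1.58 ± 0.41) and Tgfb1 (0.40 ± 0.10) were higher and Col3a1 (0.36 ± 0.18) was not called. Col3a1 was called with only the 2 groups, at an adjusted p of 0.0373. Col1a1 (0.43 ± 0.21) was not called, and it was called without vehicle replicate 5, or with only the 2 groups, at adjusted p from 0.0296 to 0.0443. Timp1 (0.82 ± 0.28) was called, but it lost its call without SD replicates 1, 3, 6, 7 or 8 or treated replicates 1, 3, 8, 10 or 11, or with a robust prior, a prior without the trend or every probe on its own, at adjusted p from 0.0517 to 0.0774. Fibroblast markers had 7 of 13 measured genes higher, 0 lower and 6 not called. With 7 higher and 0 lower adjusted over the list alone, camera gave adjusted p = 0.005, and adjusted p = 0.298 with an estimated correlation. Pi16 (1.22 ± 0.19) and Fap (0.67 ± 0.15) were higher. Monocyte and macrophage markers had 8 of 20 measured genes higher, 0 lower and 12 not called. With 9 higher and 0 lower adjusted over the list alone, camera gave adjusted p = 0.00358, and adjusted p = 0.371 with an estimated correlation. Gpnmb (1.20 ± 0.24) and Lgals3 (0.67 ± 0.16) were higher. Oxidative phosphorylation had 0 of 43 measured genes higher, 11 lower and 32 not called. With 16 lower and 0 higher adjusted over the list alone, camera gave adjusted p = 2.07e-07, and adjusted p = 0.0671 with an estimated correlation. The tricarboxylic acid cycle had 0 of 15 measured genes higher, 3 lower and 12 not called. With 3 lower and 0 higher adjusted over the list alone, camera gave adjusted p = 0.00607, and adjusted p = 0.298 with an estimated correlation. Pc (-0.69 ± 0.07) was lower. The interferon list had 0 of 15 measured genes higher, 7 lower and 8 not called. With 8 lower and 0 higher adjusted over the list alone, camera gave adjusted p = 0.00111, and adjusted p = 0.306 with an estimated correlation. Irf7 (-1.08 ± 0.21) and Psmb9 (-0.73 ± 0.13) were lower.

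Mesothelial markers had 0 of 6 measured genes higher, 4 lower and 2 not called. With 0 higher and 4 lower adjusted over the list alone, camera gave adjusted p = 0.000344, and adjusted p = 0.0586 with an estimated correlation. Msln (-1.89 ± 0.34) and Lrrn4 (-1.74 ± 0.38) were lower. Erythroid and blood markers had 0 of 7 measured genes higher, 4 lower and 3 not called. With 0 higher and 4 lower adjusted over the list alone, camera gave adjusted p = 0.00152, and adjusted p = 0.142 with an estimated correlation. Hba-a1 (-1.27 ± 0.23) and Hbb-b1 (-1.51 ± 0.27) were lower. Cardiomyocyte markers had 1 of 11 measured genes higher, 4 lower and 6 not called. With 4 lower and 1 higher adjusted over the list alone, camera gave adjusted p = 0.0373, and adjusted p = 0.116 with an estimated correlation. Without SD replicates 3 or 7, or with a prior without the trend, the cardiomyocyte list lost its call, at adjusted p from 0.0554 to 0.0697. The lists of inflammation (adjusted p = 0.184), complement (adjusted p = 0.287), redox (adjusted p = 0.147), glycolysis (adjusted p = 0.267), nitric oxide signalling (adjusted p = 0.466) and the renin-angiotensin-aldosterone system (adjusted p = 0.633) were not called. With fry, the redox list was called, at an adjusted p of 0.0487. Among their genes, Ptgs2 (1.12 ± 0.33), Ccl2 (0.84 ± 0.24), Gucy1b1 (0.45 ± 0.09), Pde5a (0.36 ± 0.09) and Npr3 (0.85 ± 0.24) were higher, and Ace (0.29 ± 0.19), Agt (0.10 ± 0.19), Agtr1a (-0.16 ± 0.19) and Gucy1a1 (0.05 ± 0.10) were not called. The lists of MHC class II (adjusted p = 0.251), endothelial cells (adjusted p = 0.314), neutrophils (adjusted p = 0.716), lymphocytes (adjusted p = 0.0613) and atrial myocytes (adjusted p = 0.456) were not called. Without SD replicates 1, 2 or 3 or treated replicates 4 or 10, or with the filter at the median or fry, the lymphocyte list was called, at adjusted p from 0.00869 to 0.0486. Median and mean differed in sign for MHC class II (-0.20 and 0.14), neutrophils (-0.24 and 0.03) and atrial myocytes (-0.43 and 0.10).

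Genes that differed between vehicle dTGR and SD were sorted by their behaviour under treatment. Treatment differences opposite in sign to the disease differences were called for 681 genes, 24.9% of the 2731, of which 352 were higher in vehicle dTGR and lower under treatment and 329 the reverse. Mt2A, Gal, Angptl4, Ankrd2, Fos, Mt1f and Tgm1 (2.37 ± 0.43 and -2.08 ± 0.39) and Tmem63c (2.75 ± 0.43 and -1.99 ± 0.39) had the largest opposite calls. Of the 681, 556 were not called between treated dTGR and SD. That test used the spread of all 3 groups, the vehicle arrays included, and this count was not made with only the 2 groups. A missing call therefore does not place a gene at the SD level, and Mt2A was called there with only the 2 groups. In both the disease and the treatment comparison, 21 other genes were called with 1 sign. Another 1194 genes, 616 higher and 578 lower, were called against SD in both transgenic groups with 1 sign and not between them, led by Nppa, Reg3g, RT1-Db1, Gbp6, Thbs4 and Ankrd23. A further 423 genes, 272 higher and 151 lower under treatment, were called between treated and vehicle dTGR and not between vehicle and SD. Among the largest differences of this class, Sult1a1, Zbtb16 (-1.67 ± 0.35), Oas1k (-1.38 ± 0.28), Rhobtb1 (-1.29 ± 0.25) and Cntfr (-1.28 ± 0.31) were lower. Serpina3n also belongs to them.

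Both comparisons share the vehicle arrays, so the overlap was set against chance. Independent lists would share 61.2 genes higher then lower and 72.3 lower then higher. Permuted residuals gave a mean of 0.01 and at most 1 opposite call. The residuals hold no group differences, so almost no gene was called in either comparison. This count therefore cannot show what sharing the vehicle arrays adds. With different vehicle arrays on each side, opposite calls numbered 190 on average over 70 splits, from 0 to 416. Same-sign calls numbered 19.5 on average, from 0 to 131. Each side then had fewer vehicle arrays, and independent lists would share 20.4 genes higher then lower and 22.8 lower then higher on average. The fall from 681 to 190 therefore does not measure sharing alone. Across genes, which are not independent replicates, r between the differences was -0.62, and -0.39 with split vehicle arrays. Permuted residuals, which hold no group differences, gave -0.55 on average, from -0.71 to -0.33. The -0.62 lies within this range, so r with shared arrays does not by itself show a reversal. The covariance was -0.0716, and -0.0513 with split vehicle arrays. Permuted residuals gave a covariance of -0.0146 on average, from -0.0242 to -0.0081, and the observed one lies beyond this range. Permuting spread the wider residuals of the vehicle arrays over all groups, so this range can understate what sharing gives. The slope of treatment on disease differences with different vehicle arrays on each side was -0.31 on average and ranged from -0.42 to -0.15 over the splits. For the comparisons sharing SD arrays, 1337 genes had calls of 1 sign, 683 higher and 654 lower, against 132 and 106 for independent lists. Split SD arrays gave 638 on average, where independent lists would share 55.3 higher and 41.3 lower. The opposite calls were 412 without vehicle replicate 4 and 1042 without vehicle replicate 7. Without vehicle replicates 6 and 7 together, they were 1418 and the slope was -0.47.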

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

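The tests of a swap, of SD rats labelled as vehicle and of mesothelial and blood content were chosen only after the result was seen; the others were written before.

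Vehicle replicates 6 and 7 lay with the treated arrays on the first component. A swap with treated rats would need treated arrays at the Hmox1 level of the other vehicle arrays, and 0 of 12 reached it. SD rats labelled as vehicle would lie near 0 on genes called in both transgenic groups, scaled to 1 at the other vehicle arrays, and the mean of the 2 arrays was 0.795 (0.865 and 0.726 over 1194 genes). On held-out genes that differ in treated rats, scaled from 0 at vehicle to 1 at treated, their mean was 0.926, between 0.669 and 1.20 for treated arrays and above -0.28 to 0.65 for the other 6 vehicle arrays, so treated rats recorded as vehicle stay possible. The held-out genes were chosen to differ in treated rats from both SD and vehicle, without a clear difference between SD and the other vehicle arrays. A milder course of disease with levels between those of SD and the other vehicle arrays would score near 0 on them. A milder course could give the same score only if it changed these genes where the fuller course did not, which was not tested. Vehicle replicate 3 at 0.65 lay just under the lowest treated array, and the labels were kept as given.

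The 1194 genes that differed from SD in both transgenic groups and not between them may hold genes near loci that differ between the rat colonies. Such blocks would place more of these genes side by side than chance, and 122 neighbouring pairs were found against a median of 124 for 10000 random sets matched on level, whose central range at the 0.05 level was 105 to 144. The bound written beforehand against blocks, at or under the random median, was met, but by less than the spread of the random sets, and the required margin was set after the value was seen. Neighbours whose symbols begin with the same letters were left out, so clusters of related genes, such as RT1 genes, were not tested. Blocks of other genes as the source of many of these genes find no support here. The design compares a single transgenic line with SD. A few linked loci or scattered single genes therefore cannot be told apart from effects of the transgenes. The difference in genotype that the design names stays open and untested.

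Mesothelial genes were lower in both transgenic groups, with list medians of -1.97 and -1.55. If biopsies held less of the heart surface, the 6 genes should move together among arrays of a group. Their mean pairwise correlation was 0.238, above 0.128, the upper bound at the 0.05 level for random sets matched on level. It was higher for some other lists, such as macrophage markers (0.406), and lower for others, such as endothelial markers (0.0338). Moving together within groups therefore cannot tell less surface tissue from a loss of these cells. The list covers the heart's own epicardium. Whether less surface tissue or a biological loss of these cells underlies the lower levels of Msln (8.46 in SD) and Upk3b (8.02) stays open. The haemoglobin score held only 2 genes, Hba-a1 and Hbb-b1, and left out Hba-a3. Less blood in the same biopsies cannot be told apart from separate changes, since haemoglobin and mesothelial scores over 28 arrays gave r = 0.0789 (permutation p = 0.686) and rho = 0.0717 (permutation p = 0.723). Without the 2 arrays farthest from the median, r was 0.183.

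Chance is an unlikely source of the 3 counts of called genes, within what 100 splits each can show. The real split alone, 1 of 100, called as many genes in each comparison. For vehicle against SD the real count was 2731 and the highest other 1240, from a split that exchanged 2 arrays. For treated against vehicle it was 1125 and the highest other 1, and for treated against SD 2001 and the highest other 287.

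Single arrays far from the 7 others of their group appeared in 19 of 372 tests, where chance gives about 1 in 20 groups, or 18.6. Vehicle replicate 5 accounted for 6 of them, with low Ankrd1 (16.15), Col3a1 (11.29), Npr3 (8.09), Ogn (13.32) and Tnnt3 (5.81) and high Lcn2 (13.82). Vehicle replicate 1 was high in Atf3 (14.64), Il6 (9.93) and the inflammatory list score (1.24), and replicate 7 in Dlst (14.91) and Pde3a (12.20). In SD, low values were Cdh19 in replicate 3 (7.59), Cxcl10 in replicate 2 (7.61), Lyve1 in replicate 6 (10.27), Osmr in replicate 1 (10.05), and Pi16 (9.99) and Tgfb1 (9.94) in replicate 8. SD replicate 4 was high in Lgals3 (10.76) and replicate 2 low in the erythroid list score (-0.70). These values are log2 intensities, and scores are means relative to SD.

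Among 13490 probes above the filter that carry no gene symbol, which enter none of the gene counts of the comparisons, 463 were higher and 526 lower in vehicle dTGR than in SD.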

How the results depend on the processing

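Leaving out vehicle replicates 6 and 7 together was chosen after the result was seen. Where an alternative was applied to the slope, to the 296 called differences of named genes or to the lists, the slope kept its sign and no called difference or list turned its direction. The filter at the median tested 284 of the 296, and leaving out the 2 vehicle arrays together was not applied to named genes. Stricter thresholds lower counts by construction. With at least 1.5-fold, 1026 genes differed between vehicle and SD, 414 between treated and vehicle and 602 between treated and SD, with 249 opposite calls. At an adjusted p under 0.01 these were 1762, 432, 1162 and 273. With an estimated correlation, camera called 1, 1 and 5 lists in these comparisons. The estimated correlations are higher than the preset one for most called lists. Both camera runs used the same data and differ only in this setting, so the fall follows from it. The calls that were lost therefore rest on the preset correlation. For treated against vehicle, fry called 4 lists and the filter at the median 2 (the cause was not tested). Without vehicle replicates 6 and 7 together, treated against vehicle gave 2065 genes, 1418 opposite calls and a slope of -0.47 (the cause was not tested).

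Leaving out each of the 28 arrays in turn gave 2467 to 2908 genes for vehicle against SD, 659 (without vehicle replicate 4) to 1558 (without vehicle replicate 6) for treated against vehicle, and 1762 to 2139 for treated against SD. Counts of lists were 15 to 18, 2 (without vehicle replicate 5) to 11, and 13 to 15. Opposite calls were 412 (without vehicle replicate 4) to 1042 (without vehicle replicate 7), and the slope -0.38 to -0.24. Leaving out vehicle replicate 5 gave 733 genes for treated against vehicle and the slope of -0.24; the causes were not tested. The gene counts for each comparison stayed within 1.5 times under the other filters, probe choices, normalizations, priors, array weights and the fit of only the 2 groups. Of the 296 calls, 29 were lost with every probe on its own, 23 without vehicle replicate 4 or 5 and 20 with only the 2 groups. Over all settings, list tests crossed the threshold to weaker in 104 values and to stronger in 46. The arrays carry no measure of background, so how close genes near the filter at an intensity of 50.2 lie to it is not known. Small differences may be less visible at that level, which was not tested.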

Other observations

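The mast cell list was not called in any comparison. Tpsb2, a mast cell tryptase gene, was lower in treated than in vehicle hearts (log2 -0.62 ± 0.16, adjusted p = 0.0105, 12 of 12 arrays), and its difference between vehicle and SD was 0.02 ± 0.17. For vehicle against SD the list had 0 of 9 measured genes higher, 0 lower and 9 not called (adjusted p = 0.893). Its mean of -0.01 and its median of 0.02 differed in sign. For treated against vehicle it had 0 of 9 measured genes higher, 2 lower and 7 not called. With 2 lower and 0 higher adjusted over the list alone, the list was not called (adjusted p = 0.561). For treated against SD it had 0 of 9 measured genes higher, 1 lower and 8 not called. With 1 lower and 0 higher adjusted over the list alone, the list was not called (adjusted p = 0.647). Adipocyte markers had 1 of 8 measured genes higher, 1 lower and 6 not called for vehicle against SD. The lipid droplet gene Cidea was lower (log2 -0.45 ± 0.09, adjusted p = 0.000256, 8 of 8 arrays) and the fatty acid binding protein gene Fabp4 was higher (0.53 ± 0.12). That list was not called for vehicle against SD (adjusted p = 0.828), treated against vehicle (adjusted p = 0.325) or treated against SD (adjusted p = 0.273), where fry gave adjusted p = 0.0349 and its median of 0.0037 and mean of -0.11 differed in sign. Of the cardiac nerve and Schwann cell list, the receptor gene Gfra3 was lower in vehicle dTGR (log2 -1.07 ± 0.25, adjusted p = 0.00161, 8 of 8 arrays), and the list was not called in these comparisons (adjusted p = 0.688, adjusted p = 0.563 and adjusted p = 0.247).

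For vehicle against SD the unfolded protein response had 2 of 16 measured genes higher, 5 lower and 9 not called. With 5 lower and 2 higher adjusted over the list alone, the list was not called (adjusted p = 0.245). Its mean of 0.08 and its median of -0.13 differed in sign. The stress transcription factor gene Atf3 was higher (log2 2.30 ± 0.42, adjusted p = 0.00012, 8 of 8 arrays), and its log2 difference was 1.71 without vehicle replicate 1. In the same comparison the chaperone gene Hyou1 was lower (log2 -0.71 ± 0.09, adjusted p = 9.51e-07, 8 of 8 arrays). For treated against vehicle the list had 1 of 16 measured genes higher, 2 lower and 13 not called. With 2 lower and 1 higher adjusted over the list alone, the list was not called (adjusted p = 0.86). Its mean was -0.11 and its median 0.00782. For treated against SD it had 0 of 16 measured genes higher, 4 lower and 12 not called. With 5 lower and 1 higher adjusted over the list alone, the list was not called (adjusted p = 0.0994). Skeletal muscle genes were not tested as a list, and Casq1 was higher in vehicle dTGR than in SD (log2 0.60 ± 0.14, adjusted p = 0.00138, 8 of 8 arrays).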
